A study of Mus musculus with 6 samples.

How the data were processed

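Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and the ends of the resulting fragments are sequenced, in 6 thymus libraries from mice aged 4 weeks. The mice were of a mixed BALB/c and C57BL6 background. The genotype label put 3 libraries in the p53 AD/- group and 3 in the p53 -/- (p53-null) group. Replicates were numbered in the order of deposition, because the labels give no replicate numbers. Nothing in the labels states that the 6 libraries of the series came from different mice, although each carries its own identifier. P-values of the permutation tests therefore measure the spread between these libraries. Those of Fisher's exact tests count single regions as independent units and do not measure that spread.

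The authors deposited 1 list of peak summits per library, so peaks are per sample and not pooled. Each line gives the position of a summit, as an interval of 1 bp, and a score, which was read as the −log10 of the peak caller's q-value: the deposited scores begin at 1.30 to 1.39, and a q-value of 0.05 corresponds to 1.30. Trim Galore 0.4.5, Bowtie2 2.3.4.2, Picard 2.9.0, MACS2 2.1.2 and the build GRCm38 are named in the submitters' processing notes, without their roles or settings. Whether reads were shifted for the transposase cut, whether duplicates were removed and whether problem regions were masked is not given in the sources used here. Peak widths, read counts and coverage were not used here, so read depth is unknown and the number of summits is the only measure of how much was detected in a library. Scores rise with depth and were used mainly to rank or filter summits within 1 library. The share of summits with a score of at least 5 was also compared between genotypes, and scores of single Y summits are given. A percentile below is the rank of a score within its own library, with 100 at the top.

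Summits on chromosomes 1 to 19 and X were extended by 250 bp on each side and overlapping windows of all libraries were merged into regions (Python 3.11.15, pandas 2.3.3). A region was called genotype-specific when all 3 libraries of one genotype and none of the other had a summit in it. A region taken alone cannot pass a test in this design, because Fisher's exact test with 3 against 3 gives at best p = 0.10. The count over all regions was therefore compared with the counts for the other choices of 3 of the 6 libraries (20 trios, forming 10 splits) and with the count expected from each library's own odds of contributing, from a Poisson log-linear model with library main effects fitted to the 20 trio counts (statsmodels 0.14.6). Differences between group means were tested with the exact two-sided permutation test over 20 relabellings, whose smallest p is 0.10, and shares of regions with Fisher's exact test (SciPy 1.17.1). Shares carry 95% Wilson intervals and counts carry exact Poisson intervals. Both cover counting error only. P-values within a family were adjusted by the Benjamini-Hochberg method.

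Genes were taken from a RefSeq table on GRCm38 that gives the start and end of 21631 protein-coding genes on these chromosomes. It gives no strand, so a start site could not be told from the other end of a gene, and a summit within 1 kb of either annotated end stood in for the planned promoter measure. A gene end without a summit is not evidence of a closed promoter, because gene models can begin upstream of the start site in use. With the coordinates as deposited, 20.6% to 25.3% of the summits of a library lay within 1 kb of a gene end. After a shift of 20 kb the share was 5.97% to 6.21%, so the summits line up with the gene table as deposited. Regions were assigned to the protein-coding gene with the nearest annotated end within 50 kb. The planned motif searches, for p53 response elements and other motifs, were not run because no genome sequence was used here.

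The 25 gene lists, the design and the rule for naming genes were fixed before the data were examined. Of 751 list entries, 747 matched the gene table, 1 of them through a synonym. The rule names Trp53, then for each genotype the 12 genotype-specific regions with the highest score percentile (the lowest of the 3 libraries) that lie within 50 kb of a named protein-coding gene, with 1 region per gene and genes without a proper symbol skipped, then list members with a genotype-specific region (up to 6 per list and genotype), the states of 6 p53 targets, and cell type markers that differ between libraries. Some of the regions this rule selects are not reported here. For each list, genotype-specific regions were compared with the other regions that had summits in exactly 3 libraries, and the share of genes with a summit at a gene end was compared between genotypes. Alternatives were extensions of 100 and 500 bp, a score of at least 5, lists of equal length (the 44492 best-scoring summits of each library), autosomes only, a looser rule of 2 of 3 against 0 of 3, summits closer than 501 bp counted once, gene ends within 500 or 2500 bp, assignment within 10 or 100 kb, and leaving out each library. A requirement that no summit of the other genotype lie within 2 kb, and the comparison of genes with a summit at a gene end in 1 genotype only, were added after the data had been examined.

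The region method was tested on simulated data built from the 73702 real regions, with the trios of 3-library regions redrawn from the model and 200 planted regions of each kind. Each planted AD/- or null region lay apart from the real ones. It had a summit in all 3 libraries of its genotype and in none of the other. That is the calling rule itself, so recovery of all planted AD/- regions (100%) and all planted null regions (100%) was fixed in advance. Planted peaks whose summit moved by 800 bp between genotypes were also called genotype-specific in 100% of cases, and 0 of them passed the 2 kb requirement. This too followed from the settings, since 800 bp exceeds the merging distance and is under 2 kb. These counts check the code and do not measure sensitivity on real libraries. Without planted regions the ratio of observed to expected ran from 0.88 to 1.39 over the 20 trios. This range came from a single draw from the model itself and so holds counting error only. The ratios of the real trios ran wider, from 0.75 to 1.55, so the model leaves out part of the variation between trios.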

Results

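The series compared regions of open chromatin in the thymus of mice that carry a p53 allele named AD, described in the series as dimeric, over a null allele (p53 AD/-) with the thymus of p53-null mice. p53 is a transcription factor that normally binds DNA as a tetramer. Each genotype was represented by 3 libraries. The AD/- libraries 1, 2 and 3 held 54618, 60160 and 44496 summits, and the null libraries 1, 2 and 3 held 54152, 55653 and 58019. The mean was 53091 ± 7943 summits in AD/- and 55941 ± 1950 in null (SD, n = 3 each), a difference within the spread between libraries (exact permutation p = 0.8, two-sided, smallest possible 0.10). AD/- library 3 had the fewest summits of the 6. Without it the AD/- mean was higher than the null mean, by 1452 summits when those on chromosomes 1 to 19 and X were counted.

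Trp53, the altered gene, had a summit just outside one annotated end in every library of both genotypes. The gene lies on chromosome 11 from 69580348 to 69591873 (GRCm38). The summit was at 69579355, 69579356 and 69579362 in the AD/- libraries and at 69579356, 69579411 and 69579362 in the null libraries, 937 to 993 bp outside the gene. Its score stood at percentiles from 79.9 to 86.5 of the library. Inside the gene, null library 2 had a summit at 69589732 and null library 3 had one at 69586468, at percentiles of 14.1 and 0.917, and the AD/- libraries had none. The summit beside Trp53 does not tell the genotypes apart and so is no check of the labels.

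The first question was whether genotype set which regions were open. The 6 lists merged into 73702 regions, of which 38374 (52.1%) had a summit in all 6 libraries and 12104 (16.4%) in 1 library alone. Regions found in all 6 libraries were at a gene end in 27.8% of cases, compared with 7.32% to 8.27% for regions found in fewer libraries. The Jaccard index, the share of regions in common, ranged from 0.667 for AD/- libraries 2 and 3 to 0.795 for null libraries 2 and 3. Pairs of the same genotype had a mean index of 0.753 and pairs of different genotypes 0.754. The difference of −0.0011 ranked 5 among the 10 ways to split the libraries into 2 groups of 3, so the libraries did not group by genotype. The split with the highest value, 0.0144, set AD/- libraries 1 and 3 with null library 1 against the other 3 libraries. With each list shortened to its 44492 best-scoring summits the value for genotype was 0.0032.

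The shares of summits at gene ends, inside genes and outside genes did not differ by more than the spread between libraries. Summits within 1 kb of a gene end made up 22.6% ± 2.41 in AD/- and 21.6% ± 0.68 in null (SD, n = 3 each; exact permutation p = 0.7). Summits deeper inside protein-coding genes made up 44.1% ± 1.69 and 44.9% ± 0.63, and those outside genes 33.3% ± 0.72 and 33.5% ± 0.32 (exact permutation p = 0.7 for each, n = 3). The highest share at gene ends, 25.3% (95% interval 24.9 to 25.7), was in AD/- library 3, the shortest list. Without that library the difference between genotypes changed sign, to −0.27 percentage points. Summits with a score of at least 5 made up 90.7% ± 1.83 in AD/- and 93.8% ± 2.35 in null. Every AD/- library lay below every null library (exact permutation p = 0.1, the smallest possible, n = 3 each). The separation was narrow, with 91.8% in AD/- libraries 1 and 2 and 91.9% in null library 1. The lowest and highest shares were 88.6% in AD/- library 3 and 96.4% in null library 2. Scores also rise with depth, which is unknown.

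The second question was which regions differed between genotypes. Summits were found in all 3 AD/- libraries and no null library in 132 regions, and in all 3 null libraries and no AD/- library in 308 regions. With scores of at least 5 the counts were 66 and 319, with lists of equal length 167 and 202, and without AD/- library 3 the direction turned, with 782 and 405. The odds of the single libraries gave an expected 99.5 and 287 regions. The ratio of observed to expected was 1.33 for AD/- (95% counting interval 1.11 to 1.57) and 1.07 for null (0.96 to 1.20). Among the 20 trios of libraries these ratios ranked 3 and 8, and trios of mixed genotype reached 1.55. The median score percentile of the AD/- regions was 8.85 and that of the null regions 10.4, compared with 55.1 for regions found in all 6 libraries. At a gene end lay 9.09% of the AD/- regions (12 of 132, 95% interval 5.28 to 15.2) and 4.22% of the null regions (13 of 308, 2.48 to 7.09), a difference that did not pass the test (Fisher's exact test, p = 0.069, two-sided).

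**Figure D1:**
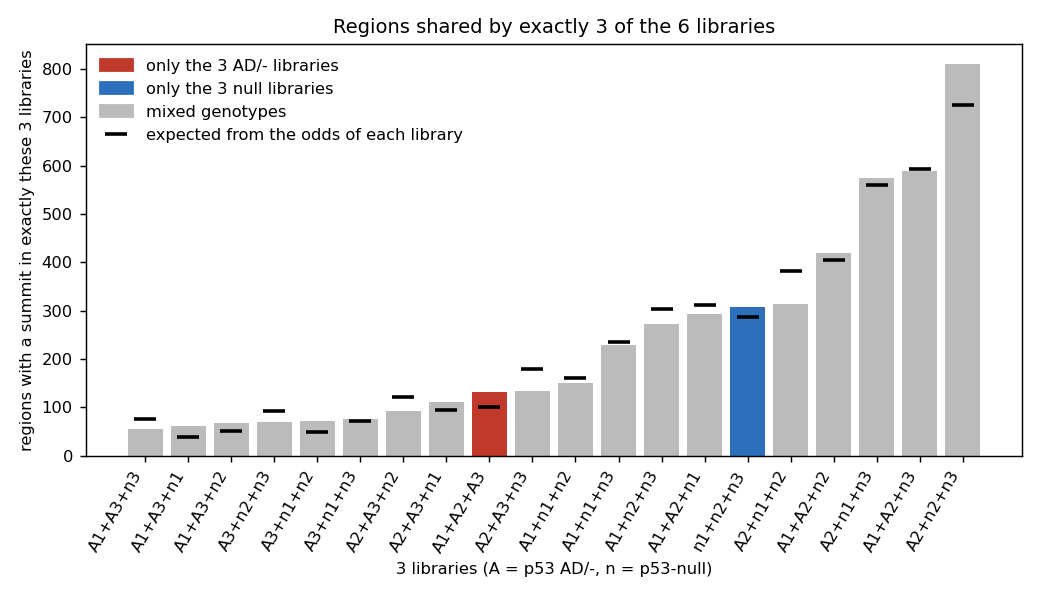
Number of regions (vertical axis) with a summit in exactly the 3 libraries named on the horizontal axis, for each of the 20 trios (bars; A, AD/- library; n, null library), with black marks at the number expected from the odds of each library. The AD/- trio (red, 132 regions) and the null trio (blue, 308 regions) lie among the trios of mixed genotype (grey), and observed and expected numbers rise together.

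Many genotype-specific regions lay next to a summit of the other genotype. Of the AD/- regions, 70 of 132 (53%) had a summit of a null library within 2 kb, and of the null regions, 107 of 308 (34.7%) had a summit of an AD/- library within 2 kb. Over all trios, the share with a summit of a library outside the trio within 2 kb was 36.6% to 79.1% in the 10 trios that include AD/- library 3 and 25.3% to 35.8% in the 10 that do not, so it went with that library and not with genotype. These shares were compared after the data had been examined. This left 62 AD/- and 201 null regions with no summit of the other genotype within 2 kb, against 47.2 and 193 expected. The ratios of observed to expected, 1.31 and 1.04, ranked 2 and 6 among all trios under the same requirement. The AD/- ratio thus stayed near its earlier 1.33. A mixed trio, AD/- library 3 with null libraries 1 and 3, ranked first, also at 1.31. The mixed trio of AD/- libraries 1 and 3 with null library 1 fell from 1.55 to 0.86. Of the 62 and 201 regions, 3 and 7 were at a gene end (4.84% and 3.48%, Fisher's exact test, p = 0.70). The median score percentile of the 62 AD/- regions was 4.92 and that of the 201 null regions 10.4.

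The 12 highest-scoring AD/- regions were near genes of several functions, and all 12 had a null summit within 2 kb. They include a region 5421 bp from Il2ra, which encodes the alpha chain of the interleukin 2 receptor (chromosome 2, position 11637371, lowest percentile 69.1), with the nearest null summit 1138 bp away. A region inside Irf8, an interferon regulatory factor of myeloid and B cell development (chromosome 8, position 120750893, lowest percentile 56.2), had a null summit 925 bp away. Another lay 13002 bp from Ddit4, an inhibitor of mTORC1 signalling induced by stress (chromosome 10, position 59964772, lowest percentile 68.0), with a null summit 966 bp away. The highest-ranked was 34119 bp from Smndc1 (lowest percentile 77.8), a splicing factor gene, followed by regions near Tesc (76.4) and Dhrs3 (73.5), a retinal reductase. Regions near Shank3, Herpud2, the mitochondrial ribosomal protein gene Mrpl1, Lyzl1, the progranulin gene Grn and the lipid kinase gene Pip5k1a followed, with lowest percentiles from 59.8 down to 43.9.

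The 12 highest-scoring null regions overlapped this set of genes. The first 3 were near Tesc, Herpud2 and Shank3, with lowest percentiles of 81.0, 63.7 and 63.5, and lay 856, 592 and 682 bp from an AD/- summit. At Tesc, on chromosome 5, the summit was near position 118037042 in all 3 AD/- libraries and near 118037898 in all 3 null libraries. Regions near Myl10 (56.8), the chemokine receptor gene Ccr3 (38.7) and Phf19 (35.9), a Polycomb-associated protein, also had an AD/- summit within 2 kb. In 5 of the 12 no AD/- summit lay within 2 kb. Among these were regions near Wnt9a, a Wnt ligand (chromosome 11, position 59302896, percentile 42.2, nearest AD/- summit 3925 bp away), Tigd2 (40.5), Iqcg (37.0, inside the neighbouring gene Lrch3) and Acbd6 (36.1). With extensions of 500 bp, 13 of the 24 regions had summits of both genotypes.

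**Figure D2:**
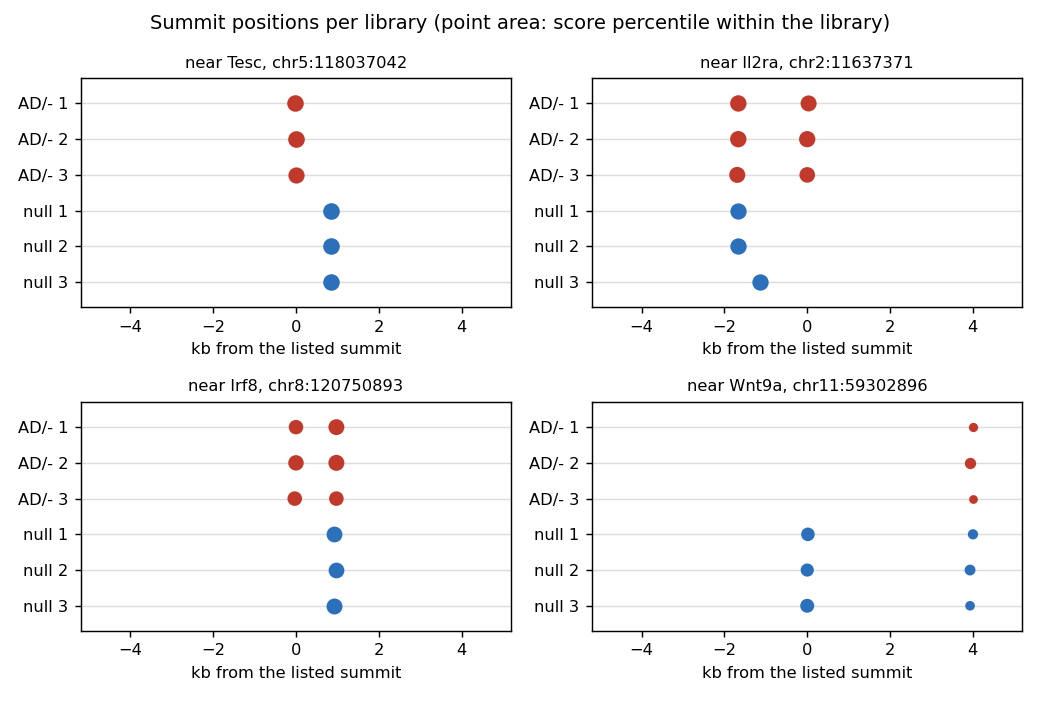
Summit positions in kb from the listed summit (horizontal axis) for each library (lines; red AD/-, blue null) at the regions near Tesc, Il2ra, Irf8 and Wnt9a, with point area rising with the score percentile within the library. At Tesc the summit of the null libraries lies 856 bp from that of the AD/- libraries, at Il2ra and Irf8 the AD/- libraries have an additional summit beside one close to a null summit, and at Wnt9a the null libraries have an additional summit 3925 bp from the nearest AD/- summit.

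Of the 693 genes in the 25 lists, 10 had an AD/- region and 11 had a null region assigned, and for 2 and 7 of them no summit of the other genotype lay within 2 kb. The T cell development list (60 genes) had the most. AD/- regions lay near Il2ra, inside Gata3, the regulator of T cell commitment (lowest percentile 23.4), and inside Foxo1 (2.24), and null regions lay near Cd5 (14.1) and Il7r, the interleukin 7 receptor gene (6.23), and inside Notch1 (5.26) and Nr4a1 (0.059). Of these, the regions at Foxo1, Il7r, Notch1 and Nr4a1 had no summit of the other genotype within 2 kb. Among the 76 three-library regions of this list, 3.95% were AD/- regions and 5.26% null regions, compared with 2.71% and 6.39% elsewhere (Fisher's exact test, p = 0.46 and p = 1). The thymic lymphoma list had an AD/- region at Gfi1b (lowest percentile 4.50, null summit 1052 bp away). Its null regions were at Stat5a (9.62, AD/- summit 596 bp away), Il7r and Notch1.

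Among 42 matched p53 targets, a single gene had an AD/- region and another a null region. The former was 6029 bp from Aen, an apoptosis-enhancing nuclease (percentile 13.4, null summit 914 bp away), and the latter inside Polk, a translesion DNA polymerase (8.74, AD/- summit 5639 bp away). The 9 metabolic lists held 265 genes, for peroxisome proliferator-activated receptor (PPAR) targets and coregulators, fatty acid oxidation, lipid synthesis, glycolysis, the TCA cycle, oxidative phosphorylation, mitochondrial biogenesis and amino acids. An AD/- region was assigned to 2 of them, Pfkp, a phosphofructokinase (6.42), and Pck1, a gluconeogenic enzyme (33.8, null summit 800 bp away), and a null region to 0 of them. Other AD/- regions were assigned to Irf8, Prss16, a thymic serine protease, and Traf1. The Traf1 region (chromosome 2, position 34928426) lay beside the null region named for Phf19 (position 34927504). Other null regions were assigned to the proapoptotic gene Bcl2l11, the interferon-induced Rsad2, Flt3, Hemgn and Lep. The regions at Irf8, Prss16, Traf1, Bcl2l11 and Lep had a summit of the other genotype within 2 kb. Over all 25 lists and both genotypes, 0 of 50 Fisher's exact tests passed an adjusted p of 0.05, 0 had an unadjusted p under 0.05, and the lowest unadjusted p was 0.064. The lists held at most 76 three-library regions (T cell development) and as few as 1 (B cell and erythroid markers). In the TCA cycle list, 1 of 3 such regions was an AD/- region, and an odds ratio of 17.9 gave p = 0.080 (Fisher's exact test). Small enrichments were therefore not detectable, and in lists with few such regions large ones were not either.

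Gene ends were open in much the same genes in both genotypes. A summit lay at an end of 55.8% ± 1.79 of the 21631 protein-coding genes in AD/- and 56.4% ± 0.10 in null (SD, n = 3 each; exact permutation p = 0.9), and 11385 genes (52.6%) had one in all 6 libraries and 8796 (40.7%) in none. Of the p53 targets, 35 of 42 had a summit at a gene end in all 6 libraries, among them Mdm2, the p53 ubiquitin ligase, the proapoptotic Pmaip1, Ccng1 and Trp53inp1. Cdkn1a, the cell cycle inhibitor, and Bbc3, a proapoptotic gene, had none in any library, although 2 and 3 regions assigned to them were found in all 6 libraries. The housekeeping gene Actb likewise had none. The mean share of p53 targets was 88.1% ± 2.38 in AD/- and 88.9% ± 1.37 in null (exact permutation p = 1, n = 3 each). Tgfa, Rprm and Ercc5 differed between libraries, and none of the 3 followed genotype.

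No metabolic list passed the test. PPAR targets had 61.9% ± 1.65 in both genotypes, oxidative phosphorylation 95.3% in both, fatty acid oxidation 93.1% and 94.3%, glycolysis 84.4% and 85.4%, the TCA cycle 92.6% and 91.4%, mitochondrial biogenesis 93.5% and 94.6%, amino acid and one-carbon metabolism 93.3% and 94.3%, and PPARs with their coregulators 84.4% and 86.7%, AD/- first. The SD of these lists was at most 3.85 points in a genotype (n = 3 each). Lipid synthesis had 84.8% ± 3.03 in AD/- and 81.8% in null, where 27 of 33 genes had a summit in each null library. In this list Elovl6, a fatty acid elongase, had a summit in AD/- libraries 2 and 3 and in no null library. All 34 DNA damage genes and 43 of 45 cell cycle genes had a summit in all 6 libraries. Apoptosis genes had 77.8% and 76.9%, thymic lymphoma genes 82.4% and 83.3%, NF-kB and inflammation genes 58.9% and 61.1%, and housekeeping genes 94.1% and 92.2%.

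T cell development genes were open in both genotypes, and shares were lower for markers of other cell types. The T cell list had a summit at the end of 57 of 60 genes in all 6 libraries, with means of 96.1% ± 0.96 in AD/- and 96.7% in null. The mean share in AD/- and null was 35.4% ± 3.61 and 39.6% ± 3.61 for B cell markers, 38.9% ± 4.81 and 41.7% for myeloid and dendritic markers, and 27.8% ± 4.81 and 33.3% for erythroid markers. It was 44.4% ± 9.62 and 50% for adipose markers, and 61.9% ± 4.76 and 63.5% ± 2.75 for mature T, NK and gamma-delta T cell markers (SD, n = 3 each; SD 0 where none is given). Without AD/- library 3 the AD/- share was 37.5% for B cell, 41.7% for myeloid, 29.2% for erythroid, 50% for adipose and 64.3% for mature T cell markers, so the myeloid and adipose shares then equalled those in null. Thymic epithelial markers had 40% ± 8.66 in AD/- and 48.3% ± 2.89 in null. AD/- library 3 had 6 of these 20 genes, against 9 to 10 in the other libraries, and lacked Krt18, Prss16 and Dll4. Without it the AD/- share was 45%. Psmb11, a proteasome subunit of cortical epithelium, had a summit in null libraries 1 and 2 alone.

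In the other direction, endothelial and mesenchymal markers had 33.3% ± 2.89 in AD/- and 26.7% ± 2.89 in null (exact permutation p = 0.2, n = 3 each), and 35% in AD/- without library 3. Sox18, an endothelial transcription factor, had a summit in AD/- libraries 1 and 2 alone, and Twist1, a mesenchymal one, in all 3 AD/- libraries and null library 2. Interferon and antigen presentation genes had 90.2% ± 3.47 and 86.4% ± 3.94 (exact permutation p = 0.3, n = 3 each). Irf7 and Ifit3, both induced by interferon, had a summit in the 3 AD/- libraries and in null library 3. No list passed: 0 of 25 exact permutation tests had an unadjusted p under 0.05, which this design cannot give, and the lowest p was 0.2.

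**Figure D3:**
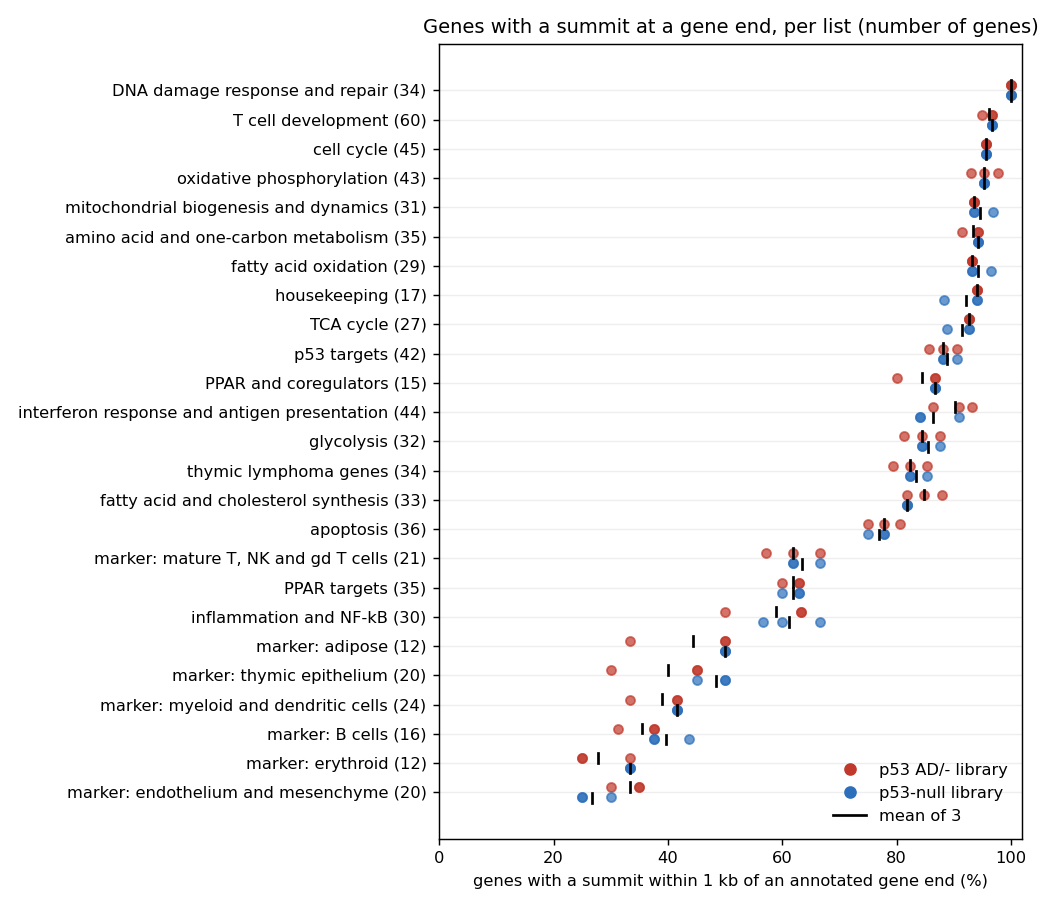
Share of genes with a summit within 1 kb of an annotated gene end, in percent (horizontal axis), for the 25 gene lists (with the number of matched genes), 1 point per library (red AD/-, blue null) and a black bar at the mean of each genotype. T cell development and DNA damage genes lie above 90% in every library, the marker lists of other cell types lie lower, and the points of the genotypes overlap or touch in every list.

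Single genes rarely had a summit at a gene end in 1 genotype alone. In AD/- only these were Ugt1a1, a bilirubin-conjugating enzyme gene, Naif1, Tmem26 and the potassium channel gene Kcnh8. In null only they were Cfap126, the channel gene Hcn2, Dlg5, Csmd3, Ly6m, Wnt8a and Foxb2. These 4 and 7 genes compare with 1 to 29 over the 20 trios of libraries, among which AD/- ranked 16 and null 10. The ranks are of raw counts, not adjusted for the odds of each library. Trios that include AD/- library 3, the shortest list, had 1 to 8 genes, and those without it had 5 to 29. When summits of the other genotype within 2 kb of the gene end were excluded, 2 (Ugt1a1 and Tmem26) and 5 genes remained. This comparison was chosen after the data had been examined.

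Genotype-specific regions were spread over the chromosomes. Chromosome 11, which carries Trp53, held 14 AD/- and 27 null regions (odds ratios 1.46 and 1.18 against the other three-library regions, Fisher's exact test, adjusted p = 0.90 for both). A single AD/- region (1 of 132) lay on chromosome 6 (odds ratio 0.12, Fisher's exact test, p = 0.0070), which did not pass adjustment over 40 tests (adjusted p = 0.28). The X chromosome held 3 AD/- and 4 null regions. The share of all summits on a chromosome had a lowest adjusted p of 0.57 (exact permutation tests of 20 chromosomes, n = 3 each).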

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

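The tests in this part were chosen after the result had been seen. Outside the chromosomes compared, the first 10 Mb of the Y chromosome held 5 summits in null library 1, above the 3 counts that a count of 0 allows, 4 of them at the ends of Kdm5d, Eif2s3y, Uty and Ddx3y; null library 2 had 3, AD/- libraries 1 and 2 had 1 each at Eif2s3y, and AD/- library 3 and null library 3 had 0. A candidate explanation is that null library 1 came from a male mouse and the others from females: from 2 kb inside to 0.5 kb beyond the end of Xist, the gene expressed from the inactive X chromosome, null library 1 had 0 summits and each of the other 5 libraries had 1 or 2. This window was set after the values were seen, and within 1 kb of the Xist end AD/- library 3 also had 0. The Y summits of null library 2 (scores of 15.3 to 21.1) and of AD/- libraries 1 and 2 (7.25 and 6.06), all beside Xist summits, are not explained by this and their cause was not tested. On the autosomes there were 129 AD/- and 304 null regions, so the X chromosome held few of them, and effects of sex on autosomes were not tested.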

How the results depend on the processing

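The requirement of 2 kb and the counts of single genes were added after the data had been examined. No paired analysis was possible because the labels carry no replicate numbers. The 132 AD/- regions became 83 with extensions of 500 bp, 66 with scores of at least 5, 1110 with the 2 of 3 rule and 62 with the 2 kb requirement. The 308 null regions became 202 with lists of equal length (167 for AD/-), 1745 with the 2 of 3 rule and 201 with the 2 kb requirement. Leaving out 1 library eases the rule by construction, and the counts then ran from 232 to 782 for AD/- and from 405 to 1293 for null. Without AD/- library 1, 2 or 3 they were 320, 280 and 782 for AD/- and 593, 1293 and 405 for null. Without null library 1, 2 or 3 they were 232, 266 and 301 for AD/- and 906, 779 and 682 for null. More AD/- than null regions were thus found only without AD/- library 3, the shortest list. Without that library the difference in summits on chromosomes 1 to 19 and X (AD/- minus null) also changed sign, from −2846 to 1452 (range −6381 to 1452 without 1 library; exact permutation p = 0.6, n = 2 and 3), and so did that in the share at gene ends, from 1.06 to −0.273 points (range −0.273 to 2.08). The within-minus-between Jaccard difference stayed from −0.0192 to 0.0269 over all alternatives and had both signs. Genes with a summit at a gene end in AD/- only numbered 4, 2 with the 2 kb requirement, 12 with equal lists and, without AD/- library 1, 2 or 3 or null library 1, 2 or 3, in this order 13, 10, 31, 6, 15 and 17. For null only the counts were 7, 5, 5 and 19, 53, 9, 22, 23 and 20. Beyond the eased or stricter rules, the cause was not tested. No gene list passed in any alternative run, which for gene ends says nothing of stability because the exact test cannot go below p = 0.10; no chromosome passed with equal lists (Fisher's exact test, lowest adjusted p = 0.85). Of the 24 named regions, 13 lost the contrast with extensions of 500 bp; most other alternatives could not change regions chosen for full contrast and high scores. In 16 of 200 list values at gene ends, from 11 lists, the sign changed. The planned p53 element and motif alternatives were not run, since they need a genome sequence. Summit lists without read counts limit every comparison to presence or absence at the calling threshold: a change in the height of a peak called in all libraries was not detectable.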

Other observations

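The comparison of region counts with expected numbers and other splits was planned; its ratio for both genotypes together and the other tests in this part were chosen after the results had been seen. Regions found in all 6 libraries were counted per gene by nearest gene end. The counts depend on gene length and on the distance to neighbouring genes, and no enrichment was tested. The gene with the most was Ets1, with 23, followed by Itpkb (19), an inositol kinase needed for thymocyte selection, and by Fli1, Lef1 and Prkcq with 18 each; Prkcq encodes the theta isoform of protein kinase C, which acts downstream of the T cell receptor. Many genes outside the T cell development list had similar counts, such as Hpcal1 and Pag1 with 17. After Ets1 and Lef1, the highest counts within that list were Ikzf1 with 16, Bcl11b and Satb1 with 15, Myb with 14, and Cd28 and Ikzf3 with 13. The 60 T cell development genes had a mean of 7.55 such regions, compared with 1.44 for B cell markers, 0.90 for thymic epithelial markers, 0.67 for erythroid markers and 1.49 over all protein-coding genes. The marker means given here all lie below the mean over all genes, so they are not a fair sample of the marker lists. Means of the other marker lists are not given. Single genes in those lists had higher counts, such as Ctla4 and Pecam1 with 8 each and Cebpb with 6.

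The highest-scoring genotype-specific regions tended to lie beside a summit of the other genotype. A candidate explanation is that a wide peak received its summit at another position, or more than 1 summit, in some libraries. Of the 24 top regions, 79.2% had a summit of the other genotype within 2 kb, compared with a median of 45.8% (central 95% of draws 29.2 to 66.7) in 10000 random draws of 12 and 12 genotype-specific regions near genes; this describes the pattern and, without peak widths, cannot tell 1 wide peak from neighbouring peaks, so the explanation stays open. A difference between genotypes in where summits fall was tested by counting AD/- and null regions within 1 kb of each other: relative to the product of the trio counts, 7 of the 10 splits of the libraries gave as many or more, the real one included (1.48 per 10000 products, upper 95% counting limit 3.21, highest other 2.64), so 6 pairs are too few to decide and a p53 effect on summit position stays open. Displacement by up to 2 kb leaves out 5 of the null regions, among them those near Wnt9a, Tigd2, Iqcg and Acbd6, whose nearest AD/- summits lay farther away.

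The AD/- regions exceeded the number expected, 132 against 99.5; for both genotypes together the ratio was 1.14, and 2 of the 10 splits, the real one included, gave a ratio as high (highest other 1.14); 10 splits are too few for a share under 0.05. The AD/- regions were clustered: 28.8% had another within 1 Mb, compared with a median of 16.7% (central 95% of draws 9.09 to 26.5) in 1000 random draws of three-library regions. In a separate run with 200 draws, 4 of the 20 trios, the AD/- trio among them, showed such an excess. One cluster held 5 regions on chromosome 14 from 15861682 to 16302887. The region at 16302887 lay 9039 bp from an end of Ngly1. For the others the nearest gene end, that of Oxsm, was 159623 to 376970 bp away, beyond the distance used for assignment. With clustered regions counted once in every trio, the AD/- ratio was 1.22 (95% counting interval 1.0 to 1.47). It ranked 2 among the 20 trios, whose ratios then ran from 0.75 to 1.22. Clustering may thus account for part of the size of the excess, but the rank of the AD/- trio did not fall. What the segments have in common was not tested. The median score percentile of 8.85 was within the range of the draws (6.69 to 11.2), so summits near the calling threshold cannot be told apart from a p53 effect, which also stays open.

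Within 10 Mb of Trp53 lay 9 of the 440 genotype-specific regions, compared with 59 of the 4393 other three-library regions (odds ratio 1.53, Fisher's exact test, p = 0.28, two-sided).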
